A study of Homo sapiens with 25 samples.

How the data were processed

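Bulk RNA sequencing covered 25 libraries of PGP1 cortical neurons in 6 groups of 3 genotypes (Control, G32A and R403C) and 2 days. Per the labels, the authors aligned reads to hg38 with HISAT2 2.0.5, assigned them to genes with featureCounts 1.5.0-p3 and used DESeq2 1.20.0; the gene annotation and the strand protocol are not stated. The deposited raw table holds integer counts of reads per gene. The deposited normalized table holds the authors' signal values, which equal the counts divided by 1 size factor per library (0.780 to 1.45; largest deviation 5.3e-15); it was used only for this check. The deposited table holds 24491 genes, each with a read in at least 3 libraries; 19890 have a symbol and 4601 an Ensembl ID only. Positions come from GENCODE 29 on GRCh38, which holds 22588 of the gene IDs in the same version and 24390 in any version.

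Total counts per library ranged from 10830600 to 20941657. Counts were analysed in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr by group, robust quasi-likelihood fit with 1 coefficient per group), which tested 21430 genes with 19 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 11 comparisons were each mutation against Control and R403C against G32A at each day, day 65 against day 35 in each genotype, and the 2 interactions of day and mutation. Alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), DESeq2 size factors, no filter on low counts, a filter of 1 CPM in 3 libraries, an absolute log2 fold change of at least 1, libraries of 1 day only, single clones, summed libraries of the same day, genotype and suffix, leaving out each library in turn, and a replicate block of the library-name suffix or of the replicate number in the title. The choice of tests, comparisons, gene lists and these alternatives was made before the data were examined. Fits without the 7 both-day libraries, with and without the replicate block, were added after; with it the day comparisons cannot be estimated, since no other suffix occurs at both days. The clones, G5 and F7 for G32A and D5 and G3 for R403C, were read from the library names.

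Libraries that share a suffix were checked for pairing by correlating their deviations from the group means. Within a day, r ranged from 0.26 to 0.82 for 9 pairs at day 35 and from 0.17 to 0.83 for 9 pairs at day 65. At each day 7 of the 9 correlated more with their own suffix than with any other. The group means include the both-day libraries, which stand apart, so the other libraries can correlate without being paired. The suffix was used as a replicate block, which gave 23 calls for G32A against Control at day 35 in place of 12. For the replicate number in the title, r ranged from -0.46 to 0.65 at day 35 and from 0.0037 to 0.82 at day 65, and 8 of 11 and 9 of 10 pairs exceeded 0.1. Within a group no libraries were duplicates (lowest chi-square per degree of freedom of a pair 13.4, rank correlations of 0.83 to 0.99). Pairs from different groups were not checked. The labels do not say whether replicates are separate cultures, so every p-value measures the spread between these libraries only.

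Of 45 gene lists fixed in advance, 44 had at least 5 tested members. They were tested with camera (preset correlation 0.01 between genes, and again with an estimated correlation) and with fry, adjusted over the lists of a comparison, and members were also adjusted over the list alone. List levels are means over members of log2 CPM (prior count 2) after centring each gene. Named genes were the 6 called genes per direction with the largest fold change among those with a symbol, an average log2 CPM of at least 1 and no overlap between the libraries compared, besides up to 4 called members of a list, or up to 2 members where none was called; pseudogenes, clustered protocadherins and Y-linked genes were passed over. DNM1L was always named. Some genes that these rules select are not reported here. For a group with 0 reads the fold is a bound from a floor of 3 counts over the group, and for 1 to 3 reads it is a ratio with a 95% counting interval. Overlap between the mutations was compared with 20 simulations of unchanged groups, in which 1 simulated set of Control libraries served both mutations. For each comparison the libraries were also split in every other way, or in 100 ways where more existed, and again in the ways that keep the number of libraries of each suffix in each group.

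The tests were tested on simulated data with 100 genes changed at each fold. In the comparisons of a mutation with Control, edgeR recovered 21, 20, 14 and 13 genes changed 2-fold and 61, 59, 56 and 52 changed 4-fold, for G32A and R403C at day 35 and then at day 65. For R403C against G32A it recovered 37 and 18 changed 2-fold and 78 and 67 changed 4-fold at days 35 and 65. For day 65 against day 35 it recovered 15, 16 and 22 changed 2-fold and 54, 61 and 71 changed 4-fold in Control, G32A and R403C. None had the wrong direction. No library was left out of the fit on all libraries. Y-linked genes and XIST were left out of the tables of all genes.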

Results

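RNA was sequenced from cortical neurons made from PGP1, an established human induced pluripotent stem cell line. The cells were neurally induced by blocking both arms of SMAD signalling and were then kept in a medium that maintains neural cells. Besides Control, cultures carried G32A, a change in the GTPase domain of DRP1, or R403C, a change in its stalk. DRP1 is the GTPase that divides mitochondria and peroxisomes, and its gene is DNM1L. The labels give the purpose as learning how such mutations affect the development of synapses as the neurons mature. At day 35 there were 3 Control, 5 G32A and 6 R403C libraries, and at day 65 there were 3 Control, 4 G32A and 4 R403C libraries. Total counts per library ranged from 10830600 to 20941657, with a median of 13440485. The 10 most abundant genes of a library took a median of 4.58% of its counts and at most 6.66%. Levels are given in CPM, counts scaled to a common library total, as mean ± SD with the number of libraries n, and fold changes are log2 values ± SE from edgeR.

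Each library name ends in 1 of 5 suffixes, and a single suffix occurs at both days. The 7 libraries that carry it, called the both-day libraries here, are 4 at day 35 and 3 at day 65, with at least 1 in every group: replicate 1 of each group and also replicate 2 of R403C at day 35. On the first principal component, which held 43.5% of the variance, these 7 scored between -145.6 and -60.7. Of the other 18, day 35 R403C replicate 4 scored -72.3, among them, and the rest scored between -26.1 and 107. EMX1, a transcription factor of the dorsal forebrain, averaged 0.73 ± 0.48 CPM (n = 7) in the both-day libraries and 98.1 ± 61.0 CPM (n = 18) in the others. NEUROD6, a marker of cortical excitatory neurons, averaged 0.35 ± 0.46 (0.19 ± 0.21 without day 65 R403C replicate 1) against 300.4 ± 316 CPM. In the other direction COL1A1, a collagen of connective tissue, averaged 3487 ± 3502 against 337 ± 1025 CPM, while COL1A2, the partner chain of the same collagen, averaged 190.7 ± 169 against 204.7 ± 511 CPM. The means of the other 18 rested on day 35 R403C replicate 4, without which they were 96.1 ± 77.7 CPM for COL1A1 and 89.3 ± 150.4 CPM for COL1A2 (n = 17), so COL1A2 was then also higher in the both-day libraries. HOXB8, a gene of the posterior neural tube, averaged 38.3 ± 51.2 against 0.32 ± 0.58 CPM and ranged from 0 to 131 CPM among the 7; without day 65 G32A replicate 1 their mean was 22.8 ± 33.6 CPM, and without day 35 R403C replicate 4 that of the others was 0.20 ± 0.31 CPM. The level of 20 hindbrain and spinal HOX genes was 1.77 to 5.78 in 4 of them, all from mutation cultures, and -1.51 to -0.76 in the 2 Control libraries and day 35 R403C replicate 1. The highest of the other 18 was 2.83, in day 35 R403C replicate 4. Within R403C this level was positive in every library named for clone G3 (0.40 to 4.46) and negative in every one named for clone D5 (-1.18 to -0.44). TTR, the main secreted protein of the choroid plexus, averaged 2.51 ± 5.20 against 602 ± 970.4 CPM, or 0.55 ± 0.48 without day 35 G32A replicate 1 against 397 ± 445.7 CPM without day 35 G32A replicate 3. As groups, the 26 markers of cortical excitatory neurons and layers averaged 2.90 log2 units less in the both-day libraries (difference -2.90), the 38 presynaptic genes differed by -1.76, and the 20 markers of mesenchymal and vascular cells by 2.45. Every count below was therefore also computed without these 7 libraries and with the suffix as a replicate block. The fits without them were chosen after the data were seen. Without them no suffix occurs at both days, so effects of day and of suffix cannot be told apart there and no day effect within a suffix can be estimated. With all libraries and the block, a day effect rests on these 7 alone to link the days.

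**Figure D1:**
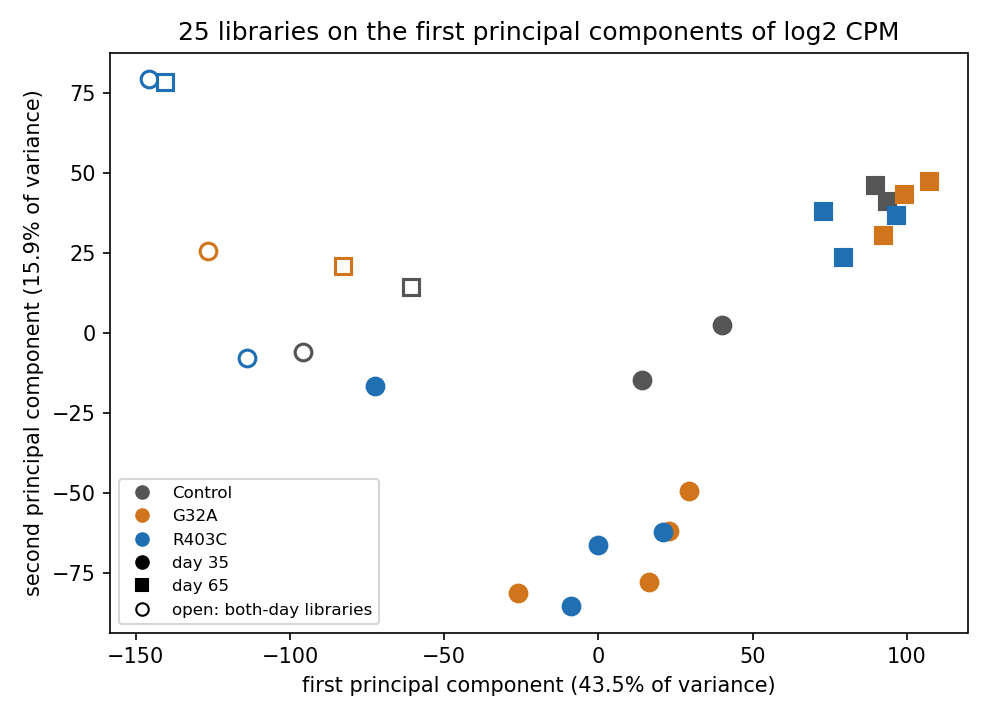
Each point is 1 of the 25 libraries placed by its scores on principal components 1 and 2 of log2 CPM, coloured by genotype, with separate markers for day and for the both-day libraries. Component 1 holds 43.5% and component 2 holds 15.9% of the variance, and the 7 both-day libraries lie at negative values of component 1.

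DNM1L (ENSG00000087470; GRCh38 chromosome 12, 32679200 to 32745650) was well expressed in every group. Its level at day 35 was 119 ± 12.8 CPM in Control (n = 3), 100.6 ± 15.4 in G32A (n = 5) and 95.1 ± 13.6 in R403C (n = 6). At day 65 it was 129 ± 25.3 CPM in Control (n = 3), 139 ± 23.8 in G32A (n = 4) and 128 ± 28.0 in R403C (n = 4). With all libraries DNM1L passed the test in none of the 11 comparisons, with log2 fold changes between -0.32 ± 0.18 (R403C against Control at day 35, adjusted p = 0.52) and 0.47 ± 0.17 (day 65 against day 35 in G32A, adjusted p = 0.15). With the both-day libraries left out DNM1L rose from day 35 to day 65 in G32A (0.65 ± 0.14; adjusted p = 0.0034) and R403C (0.54 ± 0.14; adjusted p = 0.011), where day and suffix cannot be told apart, and with the suffix as a replicate block the values were -0.01 and -0.05 (adjusted p = 0.99 and 0.90).

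The comparison of G32A with Control at day 35 asked how the GTPase-domain change altered gene expression early in maturation. In G32A 12 genes were lower and none was higher. NNAT, an imprinted gene for a small membrane protein of the developing brain, averaged 88.6 ± 1.37 CPM in Control (n = 3) and 6.86 ± 2.89 in G32A (n = 5), a log2 fold change of -3.69 ± 0.38 (adjusted p = 2.4e-05). ZNF248, a zinc-finger gene, averaged 13.2 ± 2.47 CPM in Control and had 4 reads in the 5 G32A libraries together (-7.60 ± 0.83; adjusted p = 3.5e-05). CTSF, which encodes a lysosomal cysteine protease, averaged 9.90 ± 7.25 CPM in Control and had 4 reads in G32A, all in replicate 3 (-7.20 ± 0.92; adjusted p = 0.00073). POLE4, a small subunit of DNA polymerase epsilon, fell from 23.7 ± 4.62 to 8.26 ± 2.30 CPM (-1.52 ± 0.26; adjusted p = 0.015). Every G32A library lay below every Control library for each of the 12.

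On GRCh38 NNAT, ZNF248, CTSF and POLE4 lie on different chromosomes. NNAT (ENSG00000053438) lies on chromosome 20 from 37521206 to 37523693, ZNF248 (ENSG00000198105) on chromosome 10 from 37776526 to 37858106, and CTSF (ENSG00000174080) on chromosome 11 from 66563463 to 66568841. POLE4 (ENSG00000115350) lies on chromosome 2 from 74958492 to 74970128. A further 6 genes called lower in G32A fell outside the rule for named genes and were chosen after their values were seen. With 0 reads in G32A, the zinc-finger gene ZNF502 was at least 77.2-fold lower, the noncoding LINC02864 at least 98.3-fold and the noncoding ZNF667-AS1 at least 66.7-fold, against a floor of 3 counts over the group. The zinc-finger gene ZNF471 had 1 read in G32A (203-fold lower, counting interval 35.9 to 8093) and SLITRK4, a neuronal membrane protein, had 2 reads (138-fold lower, 37.6 to 1148). PCDHGC3 fell from 11.3 ± 2.62 to 0.75 ± 0.08 CPM, but reads can be shared among clustered protocadherins, so its value is uncertain. Intervals and floors cover counting error only. POLE4 missed the threshold without Control replicate 1 or 2 or without G32A replicate 2, 4 or 5 (adjusted p 0.058 to 0.13), and ZNF667-AS1 without Control replicate 2 (0.061) or 3 (0.067) and with the suffix as a replicate block (adjusted p = 0.050; from 1.1e-06 to 0.30 over its 21 alternatives). By edgeR 1094 genes were higher and 788 lower at an unadjusted p under 0.05, DESeq2 called 20 higher and 27 lower, limma-voom 0 higher and 17 lower, and edgeR with the suffix block 4 higher and 19 lower.

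**Figure D2:**
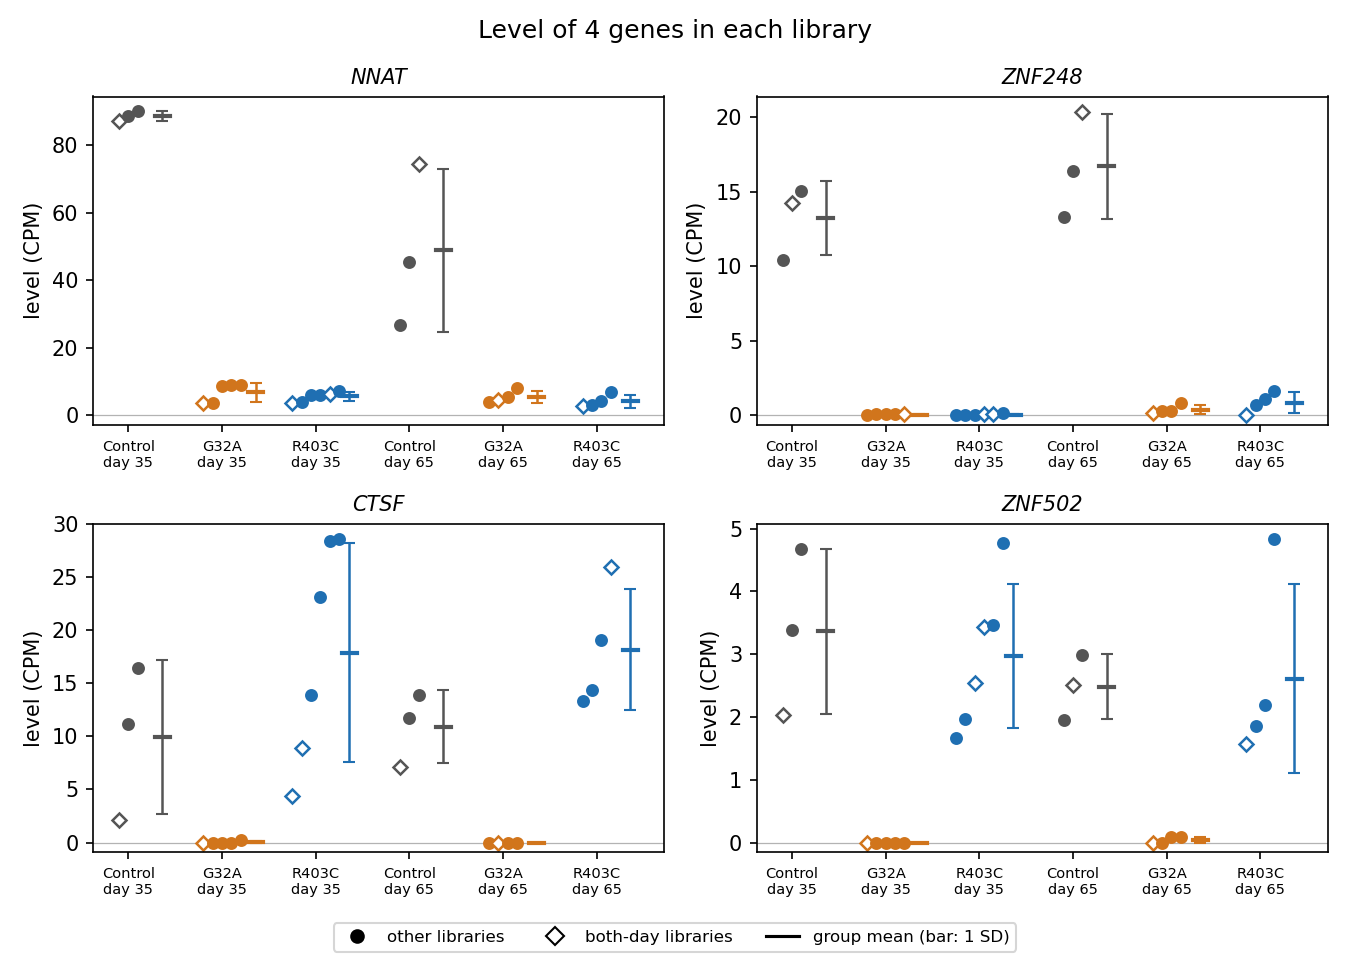
Each point is the level (CPM) of NNAT, ZNF248, CTSF or ZNF502 in 1 library, by genotype and day, with open diamonds for the both-day libraries and the group mean ± 1 SD as a bar beside the points. NNAT and ZNF248 are low in all G32A and R403C libraries at both days, whereas CTSF and ZNF502 are low in the G32A libraries only.

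Among the gene lists, 29 of 29 cell cycle genes were lower in G32A at day 35 with all libraries (camera adjusted p = 4.5e-10; adjusted p = 0.84 with an estimated correlation), and no member passed over all genes or adjusted over the list alone. MCM2 and MCM5, parts of the replicative helicase, had values of -1.03 ± 0.44 and -1.01 ± 0.44. Of the 14 choroid plexus markers 13 were higher (median 2.46; camera adjusted p = 0.00011; adjusted p = 0.81 with an estimated correlation), 0 passing over all genes and 3 adjusted over the list alone. Of the 47 postsynaptic genes 28 were lower, 0 passing over all genes and 2 adjusted over the list alone; the median was -0.08 and the mean -0.51 (camera adjusted p = 0.016; adjusted p = 0.84 with an estimated correlation). Of the 32 voltage-gated sodium and potassium channel genes 29 were lower (camera adjusted p = 0.0064; adjusted p = 0.84 with an estimated correlation) and of the 18 hypoxia genes 15 were higher (camera adjusted p = 0.0064; adjusted p = 0.81 with an estimated correlation), with no member past the threshold either way. The postsynaptic call was lost without Control replicate 2 (adjusted p = 0.15) or 3 (0.54) or G32A replicate 1 (0.32), and the channel call without Control replicate 3 (0.42) or G32A replicate 1 (0.10). None of the 29 mitochondrial fission and fusion genes, the group DRP1 belongs to, passed (camera adjusted p = 0.21); GDAP1, an outer membrane protein, had -0.63 ± 0.30 and MTFP1 1.58 ± 0.80.

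Leaving out the both-day libraries, 375 genes were higher and 269 lower in G32A (n = 4) than in Control (n = 2) at day 35, and all 12 genes above stayed called. OLIG3, a transcription factor of the dorsal hindbrain and spinal cord, rose by 5.89 ± 1.24, and CCNO, a gene of multiciliated cells, by 5.85 ± 1.42. FLG averaged 3.77 CPM in Control and 0.04 ± 0.07 in G32A, and EDNRB, an endothelin receptor of glia and neural crest, fell by 5.40 with an SE of 0.69. Of the 47 postsynaptic genes 6 fell and none rose, and 16 fell adjusted over the list alone; CAMK2B, a calcium-dependent kinase of synapses, changed by -1.71 ± 0.27 and NRGN, a calmodulin-binding protein of dendrites, by -3.29 ± 0.57. Of the 32 channel genes 4 fell (7 adjusted over the list alone), among them KCNA2 (-2.52 ± 0.47) and KCNC1 (-1.27 ± 0.28). Of the 14 choroid plexus markers 2 rose (4 adjusted over the list alone), RSPO2, a Wnt agonist (2.92 ± 0.64), and the transcription factor OTX2 (3.24 ± 0.73). Of the 18 hypoxia genes 2 rose (3 adjusted over the list alone), P4HA1, a collagen hydroxylase (1.93 ± 0.37), and VEGFA (1.40 ± 0.30). The 644 calls fell to 27 without Control replicate 2, 10 without Control replicate 3, 67, 149 and 152 without G32A replicates 2, 3 and 5, and became 1754 without G32A replicate 4 and 1735 with the suffix as a replicate block.

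The comparison of R403C with Control at day 35 asked the same of the stalk change, and it found 6 genes lower and 1 higher. NNAT fell from 88.6 ± 1.37 CPM in Control (n = 3) to 5.62 ± 1.41 in R403C (n = 6), a log2 fold change of -3.98 ± 0.36 (adjusted p = 5.2e-06). ZNF248 fell from 13.2 ± 2.47 CPM to 5 reads in the 6 libraries together (-7.57 ± 0.76; adjusted p = 1.8e-05). CCDC125 (ENSG00000183323; chromosome 5, 69280175 to 69332809), a coiled-coil protein, rose from 5.88 ± 0.69 to 12.5 ± 1.84 CPM (1.09 ± 0.19; adjusted p = 0.026); its level in G32A was 11.6 ± 1.93 CPM. The other 4 genes called lower were chosen after their values were seen. ZNF667-AS1 had 0 reads in R403C and was at least 82.5-fold lower, ZNF471 had 1 read (251-fold lower, counting interval 44.3 to 10006), LINC02864 had 1 read (364-fold lower, 64.6 to 14471) and SLITRK4 had 6 reads (56.8-fold lower). ZNF667-AS1 (chromosome 19, 56477250 to 56500666) lies next to ZNF471 (56507843 to 56530221), and as an antisense gene its value is uncertain. All 7 separated every R403C library from every Control library. CCDC125 missed the threshold without Control replicate 1, 2 or 3 or R403C replicate 3, 4 or 6 (adjusted p 0.063 to 0.21), SLITRK4 without Control replicate 2 (0.054) or 3 (0.052), and ZNF667-AS1 without Control replicate 2 (0.061) or 3 (0.076). The 7 calls became 12 without Control replicate 1, 4 without Control replicate 2, 4 without Control replicate 3, 177 by DESeq2, 15 by limma-voom and 963 with the suffix as a replicate block (404 higher, 559 lower).

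With all libraries, no member of the following lists passed over all genes in R403C at day 35. Of the 38 presynaptic genes 34 were lower (median -0.89; camera adjusted p = 3.2e-07; adjusted p = 0.45 with an estimated correlation), and 0 passed adjusted over the list alone. Of the 47 postsynaptic genes 38 were lower, 6 of them passing adjusted over the list alone (camera adjusted p = 3.2e-07; adjusted p = 0.43 with an estimated correlation). Of the 32 channel genes 27 were lower (1 adjusted over the list alone; camera adjusted p = 4.4e-07), and of the 13 GABA-A receptor genes 12 were lower (0 adjusted over the list alone; camera adjusted p = 4.1e-06); both had adjusted p = 0.43 with an estimated correlation. Of the 14 choroid plexus markers 13 were higher (median 2.44; 4 adjusted over the list alone; camera adjusted p = 1.0e-05), and of the 34 genes of extracellular matrix and basement membrane 30 were higher (4 adjusted over the list alone; camera adjusted p = 4.1e-06), again with adjusted p = 0.43 with an estimated correlation. The 29 cell cycle genes were all lower (camera adjusted p = 2.1e-06; adjusted p = 0.48 with an estimated correlation), none passing either way; CCNE2 had -0.67 ± 0.30 and MCM4 -0.91 ± 0.49. Of the 26 genes of the integrated stress response 22 were higher (camera adjusted p = 0.0012; adjusted p = 0.48 with an estimated correlation), a call lost without R403C replicate 1 (adjusted p = 0.061). Of the 22 genes of mitochondrial transport 16 were lower (camera adjusted p = 0.017; adjusted p = 0.43 with an estimated correlation), and the 29 mitochondrial fission and fusion genes gave a camera adjusted p of 0.41. Fitted with the suffix as a replicate block, 12 presynaptic, 13 postsynaptic and 6 channel genes fell over all genes.

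Without the both-day libraries, 878 genes were higher and 770 lower in R403C (n = 4) than in Control (n = 2) at day 35. MAP1LC3C, an autophagy gene, rose by 7.30 ± 2.05. CHRM1, the muscarinic receptor of cortical neurons, averaged 3.18 ± 1.03 CPM in Control and 0.03 ± 0.06 in R403C, and SLA changed by -4.42 ± 0.87. Among the 38 presynaptic genes 20 fell and none rose (25 lower and 1 higher adjusted over the list alone), among them SYP, a protein of synaptic vesicles (-1.39 ± 0.22), and SV2A, another (-1.20 ± 0.20). Of the 47 postsynaptic genes 15 fell (18 adjusted over the list alone), among them CAMK2B (-2.22 ± 0.27) and GRIN2B, a subunit of the NMDA receptor (-2.62 ± 0.43). Of the 32 channel genes 11 fell (19 adjusted over the list alone), with SCN3B at -1.67 ± 0.26 and KCNC1 at -1.56 ± 0.28. Of the 13 GABA-A receptor genes 6 fell (9 adjusted over the list alone), with GABRB2 at -3.14 ± 0.62. Of the 14 choroid plexus markers 3 rose (12 higher and 1 lower adjusted over the list alone), with RSPO2 at 2.82 ± 0.64 and OTX2 at 3.16 ± 0.73. Of the 34 matrix genes 7 rose and 1 fell (20 and 1 adjusted over the list alone), with FBLN2 at 3.05 ± 0.60 and COL5A2 at 3.30 ± 0.72. The matrix level was 1.60 in R403C replicate 4, -0.11 to 0.25 in the other R403C libraries used, and -0.60 and -1.03 in Control replicates 2 and 3. Of the 26 integrated stress response genes 3 rose (7 adjusted over the list alone), with STC2 at 2.76 ± 0.52 and the cystine transporter SLC7A11 at 1.87 ± 0.41. Of the mitochondrial transport genes 2 fell (3 adjusted over the list alone): SNPH, an anchor of axonal mitochondria (-1.12 ± 0.25), and SYBU, a kinesin adaptor (-0.94 ± 0.25). Of the 29 fission and fusion genes 1 fell, GDAP1 (-0.82 ± 0.22). The presynaptic level per library was 0.60 and 0.91 in the Control replicates 2 and 3 and between -0.72 and 0.23 in the 8 mutation libraries. The 1648 calls became 157 without Control replicate 2, 6 without Control replicate 3, 581 and 1087 without R403C replicates 3 and 6, and 2957 with the suffix as a replicate block.

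**Figure D3:**
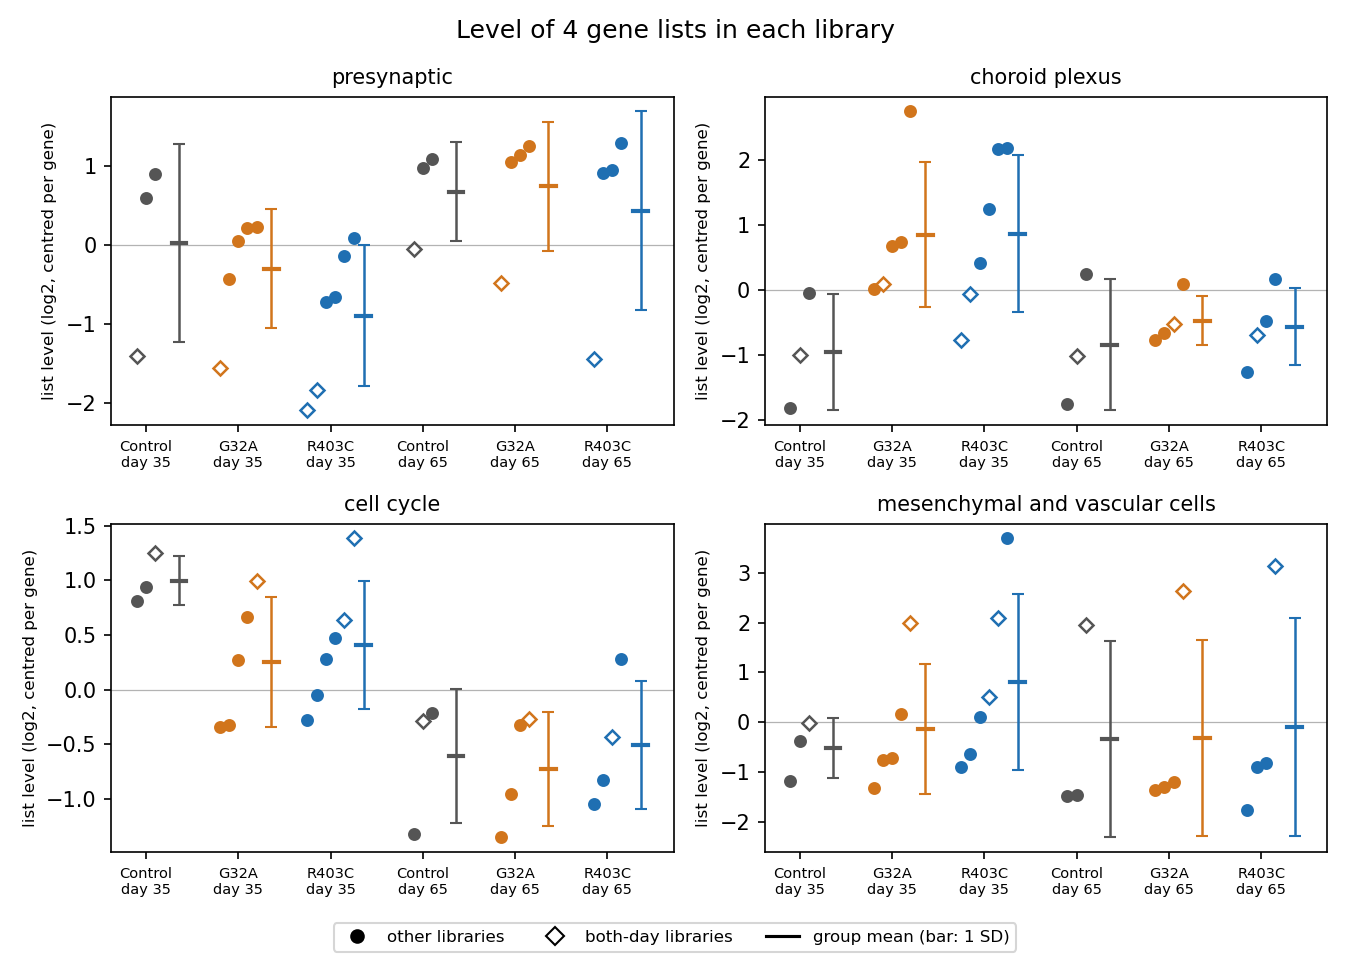
Each point is the level of a gene list in 1 library (mean of log2 CPM over the members, each gene centred on its mean over all 25 libraries) by genotype and day, with open diamonds for the both-day libraries and the group mean ± 1 SD as a bar beside the points. At day 35 the presynaptic level of the 2 Control libraries outside the both-day set is 0.60 and 0.91, above all mutation libraries of that day, whose choroid plexus levels without the both-day libraries lie between 0.01 and 2.75.

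The comparison of G32A with Control at day 65 asked whether the difference was seen later in maturation, and it found 11 genes lower and 1 higher. NNAT fell from 48.8 ± 24.1 CPM in Control (n = 3) to 5.48 ± 1.82 in G32A (n = 4), a log2 fold change of -3.16 ± 0.41 (adjusted p = 0.00086). ZNF248 fell from 16.7 ± 3.53 CPM to 20 reads (-5.40 ± 0.78; adjusted p = 0.0020). CTSF averaged 10.9 ± 3.44 CPM in Control and had 0 reads in G32A, at least 204-fold lower (adjusted p = 0.0011). A further 7 genes were chosen after their values were seen. LINC02864 and LINC01090 had 0 reads in G32A and were at least 74.7-fold and 22.3-fold lower. ZNF502 (68.3-fold lower, counting interval 18.4 to 572), ZNF471 (145-fold, 39.6 to 1204) and SLITRK4 (112-fold, 30.5 to 933) had 2 reads each. PCDHGC3 fell from 12.4 ± 4.74 to 1.62 ± 0.28 CPM, uncertain as above. The noncoding ENSG00000250658 (chromosome 4, 187304083 to 187309682) averaged 1.21 ± 0.46 CPM in Control and 5.20 ± 1.75 in G32A (2.10 ± 0.37, adjusted p = 0.024). At day 35 it averaged 4.03 ± 1.44 CPM in Control and 6.68 ± 0.78 in G32A, so both means were lower at day 65. All 12 separated the libraries of the groups.

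Single libraries ended several of these calls at day 65. SLITRK4 was lost without Control replicate 1 or 2 or G32A replicate 1, 2 or 4 (adjusted p 0.072 to 0.18), and PCDHGC3 without Control replicate 1 or any G32A replicate, 1 to 4 (0.061 to 0.098). LINC01090 was lost without Control replicate 1 or 2 or any G32A replicate (0.14 to 0.22), and ENSG00000250658 without Control replicate 2 or 3 or G32A replicate 1, 2 or 3 (0.061 to 0.31). With the both-day libraries left out all 10 calls were lower and 8 of them were among the 12. The 4 that no longer passed kept most of their difference: ENSG00000250658 (2.25 ± 0.44; adjusted p = 0.15), PCDHGC3 (-2.45 ± 0.63; adjusted p = 0.71, from -2.94 ± 0.49), SLITRK4 (adjusted p = 0.25, still at most 2 reads in G32A) and LINC01090 (adjusted p = 0.32, still 0 reads), so with fewer libraries their loss does not show a smaller difference. Those 10 calls became 6 without Control replicate 3, 4 without Control replicate 2, and 3, 3 and 5 without G32A replicates 2, 3 and 4. Without the both-day libraries and with the suffix as a replicate block, ZNF502 (-5.23; adjusted p = 0.15), ZNF471 (-7.42; adjusted p = 0.12) and LINC02864 (adjusted p = 0.12) no longer passed. DESeq2 called 23 genes with all libraries, and edgeR on the libraries of day 65 alone called 1.

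Of the 25 interferon response genes 23 were lower in G32A at day 65 (camera adjusted p = 8.8e-08; adjusted p = 0.20 with an estimated correlation), and none passed over all genes or adjusted over the list alone. OAS3 had 2 reads in G32A against 1.16 ± 1.40 CPM in Control, and MX1 had a value of -2.33 ± 0.85. Of the 23 glycolysis genes 21 were lower (camera adjusted p = 2.7e-06; adjusted p = 0.29 with an estimated correlation), with none passing either way; HK2, a hexokinase, had -0.90 ± 0.47 and PGK1 -0.52 ± 0.29. The interferon call was lost without Control replicate 3 (adjusted p = 0.36) and the glycolysis call without Control replicate 2 (adjusted p = 0.50). The 29 fission and fusion genes gave a camera adjusted p of 0.91, with SLC25A46 at 0.25 ± 0.19 and MTFR1L at 0.16 ± 0.15.

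In R403C at day 65, 4 genes were lower than in Control and 1 was higher. NNAT fell from 48.8 ± 24.1 CPM (n = 3) to 4.23 ± 1.98 (n = 4), a log2 fold change of -3.53 ± 0.41 (adjusted p = 0.00052), and ZNF248 fell from 16.7 ± 3.53 to 0.87 ± 0.71 CPM (-4.23 ± 0.73; adjusted p = 0.034). The other 3 genes were chosen after their values were seen. ZNF471 had 1 read in R403C (290.2-fold lower, counting interval 51.5 to 11517) and LINC02864 had 0 reads (at least 74.8-fold lower). ENSG00000250658 averaged 1.21 ± 0.46 CPM in Control and 5.66 ± 2.56 in R403C (2.22 ± 0.37, adjusted p = 0.030). Its day 35 means were 4.03 ± 1.44 CPM in Control and 6.22 ± 1.00 in R403C. All 5 separated the libraries of the groups. ZNF248 missed the threshold without Control replicate 1, 2 or 3 or R403C replicate 2 or 4 (adjusted p 0.076 to 0.23), and ENSG00000250658 without Control replicate 2 or 3 or R403C replicate 1 or 4 (0.053 to 0.38). The 5 calls became 3 without Control replicate 2, Control replicate 3 or R403C replicate 4, 15 by DESeq2 and 10 by limma-voom. Leaving out the both-day libraries, 2 remained, NNAT (-2.93 ± 0.39) and ZNF248 (-3.65 ± 0.53), and leaving out Control replicate 2 or 3 or R403C replicate 2 or 3 as well left 0 calls by edgeR; without R403C replicate 4 there was 1. The 3 calls lost without the both-day libraries did not shrink: ENSG00000250658 was at 2.56 ± 0.44 (adjusted p = 0.10), and ZNF471 and LINC02864 (adjusted p = 0.078 each) still had at most 1 read and 0 reads in R403C.

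All 13 mitochondrially encoded proteins were higher in R403C at day 65 (camera adjusted p = 5.0e-06; adjusted p = 0.60 with an estimated correlation), and none passed over all genes or adjusted over the list alone; MT-ND3 had 0.53 ± 0.28 and MT-CO3 0.53 ± 0.30. Under a replicate block of the suffix, 8 of the 13 passed adjusted over the list alone. Of the 83 cytosolic ribosomal proteins 76 were lower (camera adjusted p = 5.0e-06; adjusted p = 0.98 with an estimated correlation), with RPS15A at -0.56 ± 0.30 and RPL35A at -0.27 ± 0.17. Of the 25 interferon response genes 21 were lower (camera adjusted p = 0.00031; adjusted p = 0.60 with an estimated correlation), with MX1 at -1.78 ± 0.83 and ISG15 at -0.80 ± 0.41. No ribosomal or interferon gene passed either way. The mitochondrial call was lost without Control replicate 3 (adjusted p = 0.069) or R403C replicate 1 (0.33), the ribosomal call without Control replicate 2 (0.51) or 3 (0.49) or R403C replicate 4 (0.12), and the interferon call without Control replicate 3 (0.92) or R403C replicate 4 (0.26). The fission and fusion genes gave a camera adjusted p of 0.52, with MTFR1L at 0.26 ± 0.15 and OMA1 at 0.44 ± 0.33.

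The comparison of R403C with G32A at day 35 tested directly which genes differed between the mutations, and 7 genes were higher in R403C. CTSF averaged 17.9 ± 10.3 CPM in R403C (n = 6) against 4 reads in the 5 G32A libraries (8.05 ± 0.90; adjusted p = 0.00020) and POLE4 19.9 ± 7.62 against 8.26 ± 2.30 CPM (1.27 ± 0.23; adjusted p = 0.047). A further 3 were chosen after their values were seen: ZNF502 (2.98 ± 1.15 CPM against 0 reads), IQCA1 (1.63 ± 0.61 CPM against 1 read) and PCDHGC3 (26.6 ± 19.4 against 0.75 ± 0.08 CPM). Every R403C library lay above every G32A library for all 7. POLE4 missed the threshold without G32A replicate 2, 3, 4 or 5 or R403C replicate 1, 2, 4 or 5 (adjusted p 0.057 to 0.27) and without the both-day libraries (1.06 ± 0.18), and IQCA1 without any G32A replicate, 1 to 5, or R403C replicate 4 (0.054 to 0.15). None was lower by edgeR, with 197 genes higher and 81 lower at an unadjusted p under 0.05; DESeq2 called 17 higher and 1 lower, and limma-voom 6 higher and 0 lower. Of the 38 presynaptic genes 33 were lower in R403C (camera adjusted p = 3.7e-08; adjusted p = 0.52 with an estimated correlation), with 0 passing either way; SV2B had 2.23 ± 1.06 and RAB3C -1.22 ± 0.61. Of the 20 markers of mesenchymal and vascular cells 18 were higher (camera adjusted p = 0.00016; adjusted p = 0.52 with an estimated correlation), a call lost without R403C replicate 4 (adjusted p = 0.21); POSTN, a matrix protein, had 3.97 ± 1.78 and DCN, a proteoglycan, 2.81 ± 1.38.

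At day 65, 5 genes were higher in R403C than in G32A. CTSF averaged 18.2 ± 5.74 CPM in R403C (n = 4) against 0 reads in G32A (n = 4; adjusted p = 0.00070). A further 2 were chosen after their values were seen: ZNF502 (2.61 ± 1.51 CPM against 2 reads) and PCDHGC3 (13.4 ± 7.71 against 1.62 ± 0.28 CPM; 3.05 ± 0.47; adjusted p = 0.0081). All 5 separated the libraries. PCDHGC3 missed the threshold without any of the 4 G32A replicates, 1 to 4 (adjusted p 0.052 to 0.087), and without the both-day libraries (2.81 ± 0.59). None was lower by edgeR, with 176 genes higher and 99 lower at an unadjusted p under 0.05; DESeq2 called 9 higher and 2 lower, limma-voom 4 higher and 0 lower, and edgeR with the suffix as a replicate block 6 higher and 2 lower. Without the both-day libraries there were 6 calls, which became 4 without R403C replicate 2 and 2 without any of G32A replicates 2, 3 and 4 or R403C replicates 3 and 4. All 13 mitochondrially encoded proteins were higher in R403C (camera adjusted p = 2.0e-06; adjusted p = 0.96 with an estimated correlation), none passing either way, with MT-ND3 at 0.49 ± 0.25 and MT-ND4L at 0.41 ± 0.27; the call was lost without G32A replicate 4 (adjusted p = 0.10) or R403C replicate 1 (0.38).

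At day 35 the mutations shared 6 lower genes of the 12 in G32A and 6 in R403C: NNAT, ZNF248, ZNF471, LINC02864, SLITRK4 and ZNF667-AS1. Independent lists of those sizes would share 0.0034 genes. In 20 simulations, unchanged groups were compared with the same 3 simulated Control libraries and shared 0. No gene was changed in them, so few calls could arise. That 0 cannot show how much sharing a common Control brings among called genes. At day 65 they shared 4 lower genes (NNAT, ZNF248, ZNF471 and LINC02864) and 1 higher gene (ENSG00000250658), again with 0 shared in the simulations. A missed threshold was not a recovery: at day 65 SLITRK4 had 2 reads in G32A and 9 in R403C against 164 in Control. ZNF667-AS1 had 1 and 0 reads against 100. LINC01090 had 3 reads in each mutation at day 35 against 38 in Control, and 8 in R403C at day 65 against 49. POLE4 in G32A at day 65 was 2.25-fold lower than in Control. Because both comparisons use the same Control libraries, fold changes correlate without any effect. Across 21430 genes, which are not independent, r was 0.83 at day 35 against 0.64 to 0.68 in the simulations, and 0.58 at day 65 against 0.56 to 0.60. These simulations hold no suffix effects, which the mutations also share. With the suffix as a replicate block, simulated after the data were seen, r was 0.86 at day 35 against 0.63 to 0.67 and 0.62 at day 65 against 0.56 to 0.60. With the both-day libraries left out r was 0.82 at day 35 against 0.66 to 0.70 and 0.62 at day 65 against 0.59 to 0.63, inside the simulated range. In that fit the mutations shared 349 higher and 217 lower genes at day 35, none in opposite directions, where independent lists would share 15.4 and 9.67. The simulations with 2 simulated Control libraries again held no changed gene and shared 0, so they set no level for these counts. The shared genes fell to 5 higher and 18 lower without Control replicate 2 and to 0 higher and 3 lower without Control replicate 3, when only 1 Control library was left and the lists held 10 genes in G32A and 6 in R403C. At day 65 without the both-day libraries they shared 2, NNAT and ZNF248. With the suffix as a replicate block they shared 15 at day 35.

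Maturation in Control from day 35 to day 65 raised 2 genes and lowered none. C1QL1, a secreted complement-like protein of synapses, rose from 5.62 ± 0.34 CPM (n = 3) to 37.1 ± 23.2 (n = 3), a log2 fold change of 2.72 ± 0.41 (adjusted p = 0.029). PIK3CD, a catalytic subunit of phosphoinositide 3-kinase, rose from 23.3 ± 1.83 to 61.3 ± 11.6 CPM (1.40 ± 0.22; adjusted p = 0.032). Both separated the libraries of the days. C1QL1 missed the threshold without day 35 replicate 1, 2 or 3 or day 65 replicate 2 (adjusted p 0.066 to 0.28), and PIK3CD without any of these or day 65 replicate 3 (0.066 to 0.35). With the first 4 of these left out in turn edgeR called 0, without day 65 replicate 3 it called 1, and without day 65 replicate 1 it called 5. At an unadjusted p under 0.05, 1436 genes were higher and 1605 lower; DESeq2 called 171 higher and 165 lower, and limma-voom called 0. Fitted with the suffix as a replicate block, where only the both-day libraries link the days, 1013 genes rose and 1303 fell, and without the both-day libraries (n = 2 and 2) 1080 rose and 897 fell. Those 1977 calls became 42 and 126 without day 35 replicates 2 and 3, and 725 and 68 without day 65 replicates 2 and 3, and they cannot be told from differences between suffixes.

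The 29 cell cycle genes were all lower at day 65 in Control (camera adjusted p = 3.5e-29; adjusted p = 0.13 with an estimated correlation). None passed over all genes and all 29 fell adjusted over the list alone, and with the suffix as a replicate block 25 fell over all genes. MCM2 had -2.20 ± 0.52 with all libraries, and without the both-day libraries MCM3 fell by 2.34 with an SE of 0.52 and TYMS, the enzyme that makes thymidylate, by 1.59 with an SE of 0.41. Of the 25 interferon response genes 24 were higher (camera adjusted p = 1.0e-06; adjusted p = 0.13 with an estimated correlation), 7 passing adjusted over the list alone and 0 over all genes; without the both-day libraries, 9 rose, among them IFI6 (3.16 ± 0.63). Of the 19 astrocyte genes 15 were higher (camera adjusted p = 0.00033; adjusted p = 0.13 with an estimated correlation), 4 passing adjusted over the list alone; without the both-day libraries, 4 rose over all genes, among them ALDOC (3.45 ± 0.56) and ALDH1L1 (3.07 ± 0.59). Of the 18 hypoxia genes 15 were higher (camera adjusted p = 0.0010; adjusted p = 0.13 with an estimated correlation), 3 passing adjusted over the list alone, a call lost without day 65 replicate 2 (adjusted p = 0.065); without the both-day libraries, 6 rose, among them VEGFA (3.12 ± 0.35). By fry, which tests whether the genes of a list move one way on balance, these 4 lists had an adjusted p of 0.026. Outside the lists, BST2, an interferon-induced membrane protein, rose without the both-day libraries by 6.86 ± 1.66 and BARHL2, a homeobox gene, changed by -5.62 ± 0.75.

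In G32A 42 genes were higher and 40 lower at day 65 (n = 4) than at day 35 (n = 5). BCAN, the matrix proteoglycan brevican, rose from 1.28 ± 0.72 to 35.5 ± 20.8 CPM (4.78 ± 0.91; adjusted p = 0.029). NR4A3, an activity-regulated nuclear receptor, rose by 3.74 ± 0.83, LMO7 by 3.74 ± 0.69, ICAM5, an adhesion molecule of forebrain dendrites, by 3.38 ± 0.62, and PLXND1, a semaphorin receptor, by 3.10 ± 0.54. BCAN-AS2 (3.70 ± 0.76) lies antisense at BCAN, so its value is uncertain. LHX9, a transcription factor of the early diencephalon and pallium, fell from 28.9 ± 16.0 to 1.71 ± 0.51 CPM (-4.08 ± 0.67; adjusted p = 0.015). GJD2, a neuronal gap junction protein, changed by -3.32 ± 0.74, GPX7 by -3.30 ± 0.42, OTX2 by -2.89 ± 0.63, COL9A1, a collagen, by -2.29 ± 0.40 and POGLUT3 by -1.89 ± 0.41. For each of these genes the libraries of the days did not overlap.

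GPX7 passed without any single library. LHX9 was lost without day 65 G32A replicate 3 (adjusted p = 0.097) or 4 (0.076), and COL9A1 without day 35 replicate 2 (0.056) or 3 (0.072) or day 65 replicate 3 (0.10) or 4 (0.10). BCAN, LMO7, ICAM5, GJD2 and OTX2 were lost without day 35 replicate 2, 3, 4 or 5 or day 65 replicate 2, 3 or 4, and PLXND1 without the same libraries except day 65 replicate 2. NR4A3, BCAN-AS2 and POGLUT3 were lost without those 7 or day 35 replicate 1, over an adjusted p of 0.055 to 0.23 for these 9 genes. The 82 calls became 9, 8, 10 and 9 without day 35 replicates 2, 3, 4 and 5, and 1558, 11, 2 and 2 without day 65 replicates 1, 2, 3 and 4. Under a replicate block of the suffix, where the days are linked only by the both-day libraries, 477 genes rose and 304 fell, 21 of them among the 82, and of the genes above only GPX7, COL9A1 and POGLUT3 kept the call. DESeq2 called 1355 genes, while the edgeR calls were all lost when libraries of the same day, genotype and suffix were summed.

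With all libraries 31 of the 38 presynaptic genes were higher at day 65 in G32A (camera adjusted p = 1.5e-06; adjusted p = 0.92 with an estimated correlation), 0 passing over all genes and 11 adjusted over the list alone; SYN2, a synapsin, had 2.09 ± 0.61. Of the 32 channel genes 28 were higher and 1 rose over all genes (3 adjusted over the list alone), the pacemaker channel HCN2 (2.05 ± 0.43; camera adjusted p = 4.5e-06; adjusted p = 0.92 with an estimated correlation). The 29 cell cycle genes were all lower, 0 passing over all genes and 22 adjusted over the list alone (camera adjusted p = 2.3e-13; adjusted p = 0.92 with an estimated correlation). Of the 14 choroid plexus markers 12 were lower and 1 fell, OTX2 (6 adjusted over the list alone; camera adjusted p = 0.0048; adjusted p = 0.92 with an estimated correlation), a call lost without day 35 G32A replicate 3 (adjusted p = 0.061) and with the replicate block (0.32). Of the 29 fission and fusion genes 1 rose, SLC25A46, an outer membrane protein (0.77 ± 0.17; 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.66). HCN2 was lost without any library except day 65 replicate 1, and SLC25A46 without any except that library and day 35 replicate 1 (adjusted p 0.060 to 0.21 for both). With the suffix as a replicate block 8 presynaptic genes rose, while the fission and fusion list pointed lower (camera adjusted p = 0.011; adjusted p = 0.26 with an estimated correlation; 2 genes falling).

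Leaving out the both-day libraries, 2965 genes rose and 2925 fell at day 65 in G32A (n = 3 against 4), all 82 among them. CRYM, a thyroid hormone binding protein, averaged 0.04 ± 0.08 CPM at day 35 and 12.5 ± 6.32 at day 65, CHRM1 0.07 ± 0.10 and 12.9 ± 8.01, and OLIG3 14.1 ± 11.2 and 0.05 ± 0.10. Among the 38 presynaptic genes 27 rose and 3 fell (28 and 4 adjusted over the list alone), among them CPLX1, a regulator of vesicle fusion (2.38 ± 0.24), and SLC17A7, the vesicular glutamate transporter (4.30 ± 0.47). Of the 32 channel genes 17 rose and none fell (18 adjusted over the list alone), with HCN2 at 2.22 ± 0.28 and KCNA2 at 2.81 ± 0.44. Of the cell cycle genes 6 fell (19 adjusted over the list alone), with TYMS at -1.24 ± 0.31 and KIF20A at -1.14 ± 0.30. Of the choroid plexus markers 7 fell (8 adjusted over the list alone), with RSPO2 at -3.71 ± 0.57. Of the fission and fusion genes 5 rose and 2 fell, with INF2, a formin, at 1.53 ± 0.19 and SLC25A46 at 0.97 ± 0.15. The 5890 calls became 3571 and 3910 without day 65 replicates 3 and 4, and they cannot be told from differences between suffixes, none of which spans both days here.

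In R403C 195 genes were higher and 65 lower at day 65 (n = 4) than at day 35 (n = 6). PCDH8, a protocadherin outside the clusters, rose from 7.33 ± 4.06 to 69.2 ± 49.0 CPM (3.24 ± 0.48; adjusted p = 0.0078). GPD1 rose by 3.18 ± 0.64, MYO5B, a vesicle motor, by 3.15 ± 0.78, LMO7 by 3.10 ± 0.63, NYAP2 by 3.02 ± 0.61 and BRINP1 by 2.70 ± 0.60. NMU, the peptide neuromedin U, fell from 15.9 ± 7.57 to 2.21 ± 0.81 CPM (-2.85 ± 0.46; adjusted p = 0.0087). OTX2 changed by -2.54 ± 0.61, COL9A1 by -2.49 ± 0.40, GPX7 by -2.42 ± 0.39 and CFAP20DC by -2.05 ± 0.48. The libraries of the days did not overlap for any of these genes.

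Of these, PCDH8 passed without any single library, and NMU, COL9A1 and GPX7 were lost only without day 65 R403C replicate 3 (adjusted p = 0.070). GPD1, MYO5B, OTX2 and CFAP20DC were lost without day 35 replicate 1, 3, 4, 5 or 6 or day 65 replicate 2, 3 or 4, and LMO7, NYAP2 and BRINP1 without those except day 35 replicate 4 (adjusted p 0.054 to 0.20 for these 7). The 260 calls became 23, 561, 26, 68, 50 and 61 without day 35 replicates 1, 2, 3, 4, 5 and 6, and 1735, 23, 5 and 31 without day 65 replicates 1, 2, 3 and 4. Fitted with the suffix as a replicate block, with the days again linked only by the both-day libraries, 674 genes rose and 412 fell, 78 of them among the 260. Of the genes above PCDH8, NYAP2, NMU, COL9A1 and GPX7 kept the call. With the block MYO5B was at 0.18, GPD1 at 1.00 and LMO7 at 1.27, while PCDH8 was at 2.58, NYAP2 at 2.93 and NMU at -3.10. DESeq2 called 1427 genes and limma-voom 149, while the edgeR calls were all lost when libraries of the same day, genotype and suffix were summed.

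Of the 38 presynaptic genes 33 were higher at day 65 in R403C and 3 rose over all genes (17 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.6e-11; adjusted p = 0.40 with an estimated correlation): CPLX1 (2.47 ± 0.56), SYN2 (2.44 ± 0.58) and SV2A (1.49 ± 0.37). Of the 47 postsynaptic genes 40 were higher and 2 rose, the spine scaffold PPP1R9B (0.75 ± 0.15) and GRIN2B (2.61 ± 0.60), with 18 adjusted over the list alone (camera adjusted p = 1.4e-08; adjusted p = 0.40 with an estimated correlation). The 13 GABA-A receptor genes were all higher and 1 rose, GABRA5 (2.39 ± 0.52), with 6 adjusted over the list alone (camera adjusted p = 1.0e-05; adjusted p = 0.40 with an estimated correlation). Of the 19 astrocyte genes 2 rose (4 adjusted over the list alone), the filament gene GFAP (2.86 ± 0.61) and the glutamate transporter SLC1A2 (3.32 ± 0.73; camera adjusted p = 0.0014; adjusted p = 0.40 with an estimated correlation). The 29 cell cycle genes were all lower, 0 passing over all genes and 16 adjusted over the list alone (camera adjusted p = 3.7e-13; adjusted p = 0.40 with an estimated correlation), with UBE2C at -1.07 ± 0.31 and CDC20 at -1.10 ± 0.33. Of the 14 choroid plexus markers 12 were lower and 1 fell, OTX2 (3 adjusted over the list alone; camera adjusted p = 0.00089; adjusted p = 0.40 with an estimated correlation). CPLX1, SYN2, GRIN2B and GABRA5 were lost without day 35 replicate 1, 3, 4, 5 or 6 or day 65 replicate 2, 3 or 4, SV2A without those or day 35 replicate 2, SLC1A2 without those 8 except day 35 replicate 6, GFAP without day 35 replicate 1, 3, 5 or 6 or day 65 replicate 1, 3 or 4, and PPP1R9B without day 35 replicate 1 or 3 or day 65 replicate 2, 3 or 4 (adjusted p 0.054 to 0.21 for these 8). Under a replicate block of the suffix, 13 presynaptic and 9 postsynaptic genes rose, and the choroid plexus call was lost (camera adjusted p = 0.23).

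Without the both-day libraries, 2543 genes rose and 2678 fell at day 65 in R403C (n = 3 against 4), 259 of the 260 among them. CHRM1 averaged 0.03 ± 0.06 CPM at day 35 and 12.2 ± 5.15 at day 65. Among the 38 presynaptic genes 28 rose and 1 fell (29 and 2 adjusted over the list alone), with CPLX1 at 2.54 ± 0.24 and SLC17A7 at 4.45 ± 0.48. Of the 47 postsynaptic genes 26 rose and 1 fell (28 and 1 adjusted over the list alone), with CAMK2B at 2.58 ± 0.25 and DLGAP1, a scaffold protein, at 2.73 ± 0.29. Of the 13 GABA-A receptor genes 8 rose (8 adjusted over the list alone), with GABRA5 at 2.91 ± 0.51. Of the astrocyte genes 6 rose and 1 fell and the list call was lost (camera adjusted p = 0.082); SLC1A2 rose by 3.26 ± 0.44, GJA1, a gap junction protein, changed by -2.67 ± 0.46, and GFAP no longer passed (1.37 ± 0.55). Of the choroid plexus markers 8 fell, with RSPO2 at -2.78 ± 0.54. The 5221 calls became 2672 without day 65 replicate 3, and as in G32A they cannot be told from differences between suffixes.

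The day by G32A interaction asked whether the G32A difference changed between the days, and 0 genes passed by edgeR, with 477 at an unadjusted p under 0.05 (161 higher, 316 lower). DESeq2 called 1 gene, limma-voom 0 and edgeR with the suffix as a replicate block 0. In simulated data edgeR recovered 8 of 100 genes changed 2-fold and 30 of 100 changed 4-fold in this comparison. Of the 18 hypoxia genes 17 were lower in the interaction (camera adjusted p = 5.3e-07), the only list call over the 11 comparisons that held with an estimated correlation (adjusted p = 0.043), and no member passed over all genes or adjusted over the list alone. That call was lost by fry (adjusted p = 0.18) and, with an estimated correlation, under the suffix block (adjusted p = 0.25), without the both-day libraries (0.21) and with both (0.19); P4HA1 had -2.12 ± 0.63 and VEGFA -1.67 ± 0.69. The 25 interferon response genes were all lower (camera adjusted p = 5.3e-07; adjusted p = 0.25 with an estimated correlation), none passing, with MX1 at -4.18 ± 1.26 and IFI6 at -2.37 ± 0.90. With the both-day libraries left out, 1 gene passed, AK4, a mitochondrial adenylate kinase (-3.31 ± 0.37); its level rose from 6.47 ± 1.76 to 30.0 ± 5.39 CPM in Control and went from 34.8 ± 5.82 to 16.3 ± 3.86 CPM in G32A. That count became 0 without day 35 Control replicate 3 or day 65 Control replicate 2, 6 without day 35 G32A replicate 4, 4 without day 65 Control replicate 3, and 7 with the suffix as a replicate block.

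For the day by R403C interaction 0 genes passed by edgeR, with 747 at an unadjusted p under 0.05 (319 higher, 428 lower), and 0 by DESeq2, by limma-voom and by edgeR with the suffix as a replicate block. In simulated data edgeR recovered 1 of 100 genes changed 2-fold and 40 of 100 changed 4-fold. Of the 38 presynaptic genes 32 were higher in the interaction (camera adjusted p = 0.00031; adjusted p = 0.66 with an estimated correlation), with SV2A at 1.25 ± 0.60 and SYN2 at 1.91 ± 0.94. Of the 13 GABA-A receptor genes 11 were higher (camera adjusted p = 6.2e-05; adjusted p = 0.58 with an estimated correlation), with GABRA5 at 2.39 ± 0.84 and GPHN, the scaffold of inhibitory synapses, at 0.82 ± 0.33. Of the 25 interferon response genes 22 were lower (camera adjusted p = 6.9e-07; adjusted p = 0.34 with an estimated correlation), with MX1 at -4.14 ± 1.24 and IRF9 at -2.12 ± 0.74, and of the 18 hypoxia genes 17 were lower (camera adjusted p = 0.00062; adjusted p = 0.34 with an estimated correlation), with P4HA1 at -1.77 ± 0.62 and VEGFA at -1.80 ± 0.68. No member of these lists passed either way. The presynaptic call was lost without day 35 Control replicate 3 (adjusted p = 0.14) or day 65 Control replicate 1 (0.094), and the hypoxia call without day 65 Control replicate 2 (0.16).

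Leaving out the both-day libraries, 5 genes rose and 2 fell in the day by R403C interaction: CAMK2B (2.54 ± 0.41), ACTR3B, a subunit related to the actin nucleator (1.66 ± 0.22), the proteoglycan SPOCK1 (1.58 ± 0.25), SYP-AS1 (1.79 ± 0.28, uncertain as an antisense gene), CHRM1, AK4 (-3.08 ± 0.37) and MEGF6 (-2.09 ± 0.34). CHRM1 went from 3.18 ± 1.03 to 5.92 ± 2.55 CPM in Control and from 0.03 ± 0.06 to 12.2 ± 5.15 CPM in R403C. Adjusted over the list alone, 18 of the 38 presynaptic and 10 of the 13 GABA-A receptor genes were higher and 4 of the 18 hypoxia genes lower. The 7 calls became 1 and 0 without day 35 Control replicates 2 and 3, 2, 3, 5 and 1 without day 35 R403C replicates 3, 4, 5 and 6, 3 and 4 without day 65 Control replicates 2 and 3, and 13, 1 and 2 without day 65 R403C replicates 2, 3 and 4. With the suffix as a replicate block as well, 62 genes rose and 49 fell.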

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

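The tests of depth, of a few dominant genes and of deletion, and the splits of all libraries, were chosen before their results were seen; the tests of cell types, low depth of silent genes, clones, shared history, single Control libraries, delay and the splits that keep the suffixes were chosen after.

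The both-day libraries, which share a suffix, stood apart on the first principal component. Thinning every library to the lowest total left 97.9% of the gap, and leaving out the 100 most abundant genes left 99.6%, so neither depth nor a few dominant genes explains it. A plain loss of cortical cells would raise every other cell type alike, but the mesenchymal and vascular list was 2.45 higher in these libraries while the choroid plexus and astrocyte lists differed by -0.78 and -0.53; the gap of 3.23 between the first 2 (SE 0.52) argues against it. A differentiation of another regional and cellular outcome is a possible reading that was not tested, and the labels do not say what the suffix stands for.

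Among the genes called lower in a mutation, 22 genes and groups had at most 5 reads. The Control level would have given at least 67.0 reads in each, so low depth does not account for them. A call at so few reads already requires many expected reads, so this is not a separate test of depth. NNAT, POLE4 and PCDHGC3 were lower but not silent. Around 12 of the genes called lower, 262 other genes within 500 kb had a median log2 fold change of -0.014. The lowest median around 1 gene was -0.40, which argues against a deletion of most genes in such a window. Genes called lower were left out of the 262, and a median cannot show the loss of a few neighbours. A deletion of the gene alone, or with an adjacent gene, therefore stays possible, and ZNF471 lies next to ZNF667-AS1. For the 12 genes called lower in G32A at day 35 the loss was not private to 1 clone, since all 12 lay below every Control library in both G32A clones. The calls came from both clones pooled, which favours such genes, so losses private to 1 clone elsewhere were not tested. The Control library names carry 0 clone names and the labels do not say how any clone was derived, so a history that clones share, if they do, such as epigenetic silencing before they were separated or drift of the Control cells, could explain the difference as well as the mutation could, and this cannot be told from these data.

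Without the both-day libraries, the presynaptic medians at day 35 were -0.67 in G32A and -1.02 in R403C and the choroid plexus medians 2.70 and 2.89, calls by camera that were lost with an estimated correlation (adjusted p = 0.68 for both lists in G32A, and 0.26 and 0.49 in R403C). A single Control library does not explain the direction, since the presynaptic median stayed at -0.47 or lower against either Control library, although the counts of called genes fell to 10 and 6 without Control replicate 3. A delay of the whole time course could not be decided. Fold changes of R403C ran against the day effect of G32A (r = -0.36 across 21430 genes, which are not independent). That effect contains the day 35 G32A libraries, whose fold changes against the same Control libraries correlated with those of R403C (r = 0.82). Day and suffix also cannot be told apart here, so r cannot show a delay. The cell cycle list, with a median of -0.59, gave no rise that a delay would bring. Fewer neurons with every other cell type raised alike cannot be told, with a choroid plexus rise 2.63 above that of radial glia (SE 0.97; interval -1.65 to 6.91; 4 against 2 libraries). Cell composition and a change within neurons are therefore not separated.

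For G32A against Control at day 35, 1 of 56 splits, the real one, called at least its 12 genes, and the highest other called 0. That share, unadjusted for the other comparisons, would exclude chance only if neither a suffix nor a clone made libraries alike. The G32A libraries repeat 2 clones. The 18 splits that keep the suffixes of each group (highest other 0) are too few. For R403C against Control at day 35, 3 of 84 splits called at least the real 7. The highest other called 2964 with all 3 both-day libraries on one side, which points to structure in the libraries. Of 27 splits that keep the suffixes 1, the real one, did so (highest other 2). That is the smallest share 27 splits allow, unadjusted for the other comparisons, and the R403C libraries repeat 2 clones, so chance is not firmly excluded. With the replicate block the real grouping called 963 and the highest of the other 26 splits 948, which points to structure again. At day 65, 1 of 35 splits called at least the 12 of G32A (highest other 2), but 12 splits that keep the suffixes (highest other 0) are too few. For R403C 2 of 35 called at least the real 5, so chance cannot be excluded. The highest other called 17 with the 2 both-day libraries on one side, and with the replicate block the real grouping called 5. For R403C against G32A at day 35, 2 of 100 splits called at least 7, the highest other 2169 with 3 both-day libraries on one side, again pointing to structure. Of 100 splits that keep the suffixes 1, the real one, did so (highest other 1). With the replicate block the real grouping called 10 and the highest other of these 8. Chance is excluded only if libraries of the same clone count as independent, and each mutation has 2 named clones. At day 65, 1 of 35 called at least 5 (highest other 0), but 12 splits that keep the suffixes (highest other 0) are too few.

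For day 65 against day 35 in Control only 10 splits exist, of which 1, the real one, called at least 2 genes and the highest other 0; these are too few to exclude chance. In G32A 1 of 100 splits called at least 82 (highest other 4), but only 2 splits keep the suffixes (highest other 0), too few to exclude chance. In R403C 6 of 100 called at least 260, so it cannot, and the highest other called 6815 with 3 both-day libraries on one side, which points to structure; with the replicate block the real grouping called 1086, and 3 splits that keep the suffixes (highest other 40) are too few. For the interactions with G32A and R403C the real count was 0, which every split reaches by definition, so the splits test nothing there. The highest others called 297 and 13.

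Single libraries stood apart from the rest of their group in 13 of 60 groups and measures, where chance marks about 1 in 20 groups, or 3. Of the 13, 10 are measures of both-day libraries, all from day 65 G32A replicate 1 or day 65 R403C replicate 1. Day 65 G32A replicate 1 had total counts of 20.9 in units of 1e6 where the others had 10830600 to 12032676 counts, a first component of -83.0 against 92.1 to 107, a presynaptic level of -0.48 against 1.06 to 1.26, a cortical excitatory level of -2.64 against 0.98 to 1.45, a mesenchymal level of 2.64 against -1.37 to -1.21 and DNM1L at 103.9 CPM against 149 to 155. Day 65 R403C replicate 1 had 6.66% of counts in 10 genes against 4.16 to 4.47%, a first component of -140.5 against 72.8 to 96.3, a presynaptic level of -1.44 against 0.92 to 1.30 and a cortical excitatory level of -2.04 against 1.11 to 1.60. Day 35 G32A replicate 3, outside the both-day set, had a choroid plexus level of 2.75 against 0.01 to 0.74 and CTSF at 0.28 CPM against 0, and replicate 4 had ZNF248 at 0 CPM against 0.070 to 0.083. Between the mutations 7 genes differed at day 35 and 5 at day 65, and the hypoxia list in the day by G32A interaction had an adjusted p of 0.043 with an estimated correlation, lost under the suffix block (0.25), without the both-day libraries (0.21) and by fry (0.18).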

How the results depend on the processing

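The fits without the both-day libraries were chosen after the data were seen; all others were chosen before.

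DESeq2 called 47 (G32A) and 177 (R403C) genes against Control at day 35, 23 and 15 at day 65, 18 and 11 between the mutations at days 35 and 65, 336, 1355 and 1427 for the day in Control, G32A and R403C, and 1 for the day by G32A interaction. Limma-voom called 15 and 10 for R403C against Control at days 35 and 65, and 0 and 149 for the day in Control and R403C.

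The suffix as a replicate block gave 23 and 963 calls for G32A and R403C at day 35, 8 between the mutations at day 65, 2316, 781 and 1086 for the day in Control, G32A and R403C, and 15 genes shared at day 35. It turned the direction of 1 list, fission and fusion for the day in G32A, which had not passed with all libraries (adjusted p = 0.66) and passed as lower with the block (adjusted p = 0.011; adjusted p = 0.26 with an estimated correlation). Of 205 named gene results it weakened 22 and strengthened 31, and of 47 lists 2 lost the call, choroid plexus for the day in G32A and R403C. The title number as a replicate block gave 189 and 2 for R403C at days 35 and 65, and 384, 2173 and 2758 for the day in Control, G32A and R403C.

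Summing libraries left 2 and 0 calls for R403C at days 35 and 65, and 1, 0 and 0 for the day in Control, G32A and R403C. Libraries of day 65 alone left 1 for G32A, 0 for R403C and 2 between the mutations. Clone F7 alone left 3 for G32A and clone G3 alone 3 for R403C at day 35.

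Leaving out the both-day libraries gave 644 and 1648 calls for G32A and R403C at day 35, 2 for R403C at day 65, 1977, 5890 and 5221 for the day in Control, G32A and R403C, 1 and 7 for the interactions, and 566 and 2 genes shared at days 35 and 65. DNM1L passed for the day in G32A (0.65; adjusted p = 0.0034) and R403C (0.54; adjusted p = 0.011), against 0.15 and 0.16 with all libraries. With the replicate block as well, calls were 1735 and 2957 at day 35, 7 and 2 at day 65, 2 between the mutations at day 65, and 7 and 111 for the interactions; the day comparisons have no value there, because no suffix then spans both days. The cause was not tested.

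Of 151 gene set tests past the threshold, 1 stayed with an estimated correlation and 5 by fry, and 132 to 177 with 1 library left out. That gave 10 to 14 and 4 to 12 calls for G32A and R403C at day 35, 8 to 11 and 3 to 5 at day 65, 5 to 8 and 4 to 5 between the mutations, 0 to 5, 2 to 1558 and 5 to 1735 for the day in Control, G32A and R403C, and 0 for the interactions. DNM1L ranged from -0.31 to -0.16 and from -0.39 to -0.24 at day 35, from -0.04 to 0.24 and from -0.15 to 0.13 at day 65, from -0.16 to -0.02 and from -0.23 to 0.02 between the mutations, from -0.03 to 0.26, 0.39 to 0.57 and 0.34 to 0.55 for the day, and from 0.21 to 0.49 and 0.17 to 0.45 for the interactions.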

Other observations

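The observations here were picked after the results were seen. The calls come from the planned comparisons, whereas the simulations with the suffix block and the fits without the both-day libraries were added after. In both mutations NNAT, ZNF248, ZNF471 and LINC02864 were nearly silent or much lower at both days, while CTSF and ZNF502 were nearly silent in G32A alone. Fold changes of the mutations correlated more at day 35 (r = 0.83 across genes) than 20 simulations with the same Control libraries and no suffix effects gave, whereas at day 65 they did not (r = 0.58); with the suffix as a replicate block r lay above the simulations at both days (0.86 and 0.62), without the both-day libraries it did so at day 35 (0.82) and not at day 65 (0.62), and part of any excess may come from suffixes that the mutations share. Outside the both-day libraries, the range of 10 to 1754 calls for G32A at day 35 when 1 more library was left out leaves the size of that difference open.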
